A study of Homo sapiens with 6 samples.

How the data were processed

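Total RNA from breast cancer cell lines was amplified to biotinylated cRNA and hybridised to Illumina bead arrays, per the labels' protocols. The series has 6 arrays. MDA-MB-231 cells have 2 arrays labelled as carrying hairpin shRNA-1 against SETDB1 and 2 labelled control, and MDA-MB-453 cells have 1 array labelled shRNA-3 and 1 labelled control. All 6 carry the same batch label, and the files name no slide, so neither could be tested as a batch. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

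The authors deposited a table of non-normalized probe intensity values, with no background correction named in it, for 48107 probes per array. Beside each intensity the deposited table gives a detection p-value, as named per the file headers. The authors also deposited processed values on a log2 scale. These were checked against the intensities and equal the quantile-normalized log2 intensities of the same 6 arrays, with no background correction, to within 5.26e-09 on every array. The median of each of the 6 processed columns is 5.71. The scale, direction and lack of centring of the processed values are therefore known. The program and version that made the intensities and the detection p-values are not given in the sources used here.

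Probes were named through GEO's platform annotation, which can be old. It gives 1 gene symbol for 30113 probes, several for 8 and none for 17986, and probes with several or none were not tested. The Entrez identifiers of 30074 probes were found in NCBI RefSeq's gene table for the assembly GRCh38.p14, and 0 symbols changed. That table was used only for names and for the order of genes along chromosomes, since the array files name no genome build, and no coordinates are given.

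Background was corrected and arrays were normalized with limma 3.58.1 in R 4.3.3, using normexp with negative controls inferred from the detection p-values, an offset of 16, quantile normalization over the 6 arrays and log2. A probe was kept when its detection p was below 0.05 on at least 2 of the 6 arrays, which left 17668 named probes. For each gene the probe with the highest mean log2 intensity was tested, giving 13022 genes. Of the 3593 genes with over 1 such probe, 20 had probes called in opposite directions, and 0 of the genes named in the text were among them. A probe with a detection p of 0.05 or more is called not detected. Where a gene was not detected on any array of a group, its fold is given as a lower bound, at least N-fold, with each dim array raised to the lowest normalized value among its detected probes.

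Differences were tested on the log2 scale with limma (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over the 13022 genes, threshold 0.05). A fit with a mean for each of the 4 groups gave the contrast of MDA-MB-231 arrays labelled knockdown against control, and the difference of that effect from the one in MDA-MB-453. It has 2 residual degrees of freedom before moderation and a prior worth 6.52. All its replicates are MDA-MB-231 arrays, and the MDA-MB-453 arrays were assumed to vary like them. An additive model of cell line and arm, with 3 arrays against 3, gave the effect across lines. Within MDA-MB-453 there is 1 array per arm, so differences are given without p-values. For a single gene the smallest p that an exact permutation of 2 against 2 arrays can give is 0.333, so every p-value below that rests on the moderated spread shared between genes.

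Before the data were examined, 25 gene lists were fixed: H3K9 methylation and SETDB1 partners, Polycomb group, MYC network, MYC target genes, G1/S and DNA replication, G2/M cell cycle, CDK inhibitors and p53 target genes, apoptosis regulators, mesenchymal and matrix, epithelial junction and keratin, breast cancer stem cell markers, interferon-stimulated, inflammatory cytokines and NF-kB targets, hypoxia and glycolysis, unfolded protein response and ATF4 targets, cholesterol biosynthesis, immediate-early, zinc finger (ZNF) genes, cancer-testis genes, clustered protocadherins, histone genes, ribosomal proteins, mitochondrial oxidative phosphorylation, and markers of each of the 2 cell lines. All 25 had at least 5 measured members. Lists were tested in MDA-MB-231 with limma's camera, which sets a list against all other genes, with a preset correlation between genes of 0.01, and again with an estimated correlation. The version with an estimated correlation rests on the 2 residual degrees of freedom. Its larger p-values therefore do not measure the effect of correlation between genes alone. In MDA-MB-453 the median of a list was placed among 10000 random lists of the same size matched on mean intensity. The name MIZ1 in the MYC network list was read as ZBTB17, which was set after the data were seen, and the pattern for cancer-testis genes also took in SSX2IP, whose product binds an SSX protein.

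The genes named were chosen by a rule fixed at the same time. It takes SETDB1, BMI1 and MYC always, the 12 largest rises and 12 largest falls in MDA-MB-231 among genes past the test whose arrays did not overlap between arms and which were detected on both arrays of the higher arm, the 8 largest differences in each direction in MDA-MB-453 among genes detected on the higher array, up to 6 in each direction across lines with the same sign in both, and the 4 largest in each direction for the difference between lines. From each list it takes up to 4 members with the smallest p. After the results were seen this was set to 4 from lists past the camera test and 2 from the others. Symbols starting with LOC or HS. were left out. Genes named outside this rule are line markers, EPCAM as a member of the epithelial list that fell, and families marked as chosen after their values were seen.

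The procedure was tested on simulated data for the same 13022 genes with 200 changed. For MDA-MB-231 it recovered 0% of changes of 0.5 on the log2 scale, 95.5% of changes of 1 and 100% of changes of 2, with 1, 16 and 11 false calls. In the data 5103 genes were called. The adjusted threshold depends on the share of genes changed, so the recovery with 200 changed does not describe that comparison. For the effect across lines the procedure recovered 14%, 100% and 100%, with 1, 11 and 8 false calls. The simulated change was the same in both lines. A difference of effect between the lines adds to the spread in that model, so these values do not carry over to the data. Alternatives tried were other background, normalization, filter, variance and probe choices, the replicate number as a block, each MDA-MB-231 array left out, and other set tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.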

Results

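Gene expression was measured on 6 Illumina bead arrays of 2 breast cancer cell lines. MDA-MB-231 is a mesenchymal-like, hormone receptor-negative line, and MDA-MB-453 is a luminal-like line that expresses the androgen receptor. The MDA-MB-231 arrays comprised 2 labelled as SETDB1 knockdown with hairpin shRNA-1 and 2 labelled control, and the MDA-MB-453 arrays 1 labelled knockdown with hairpin shRNA-3 and 1 labelled control. Line and hairpin therefore changed together. Between 19230 and 21238 of the 48107 probes were detected per array, with median intensities of 47.9 to 60.4. Values below are normalised log2 intensities of 13022 genes, differences are knockdown minus control as labelled, and errors of differences are standard errors from limma.

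SETDB1, the histone methyltransferase that the hairpins target, was not measurably lower on its probe. In MDA-MB-231 it stood at 7.41 ± 0.01 (SD, n = 2) on the control arrays and 7.25 ± 0.05 (SD, n = 2) on those labelled knockdown, a difference of -0.16 ± 0.16 (SE; 95% confidence interval -0.53 to 0.22; limma adjusted p = 0.493). In MDA-MB-453 it was 8.98 on the control array and 8.73 on the other, a difference of -0.25. Both MDA-MB-231 arrays labelled knockdown lay below both controls, and the interval allows a fall of at most 1.45-fold. Only 1 probe names SETDB1, and its place relative to the hairpins' targets was not analysed here. The arrays are called "labelled knockdown" for this reason, and every direction given below rests on that label.

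BMI1 and MYC, which the series title names beside SETDB1, differed from each other. BMI1, a Polycomb group protein of the complex that ubiquitinates histone H2A, fell by 1.18 in MDA-MB-231 (SE 0.19, adjusted p = 0.0015), from 11.26 to 10.08, with both arrays labelled knockdown below both controls. In MDA-MB-453 it was lower by a similar amount, with a difference of -1.14 between 1 array and 1 array. Region-wide shifts along chromosomes, described below, were present in the MDA-MB-231 arrays, and how far they bear on the BMI1 fall was not analysed. Across both lines the BMI1 difference was -1.17 with a limma adjusted p of 0.0564 (unadjusted p = 2.78e-04), which missed the threshold. The adjustment gave many other genes this same value, so it does not rank BMI1 among them. MYC, the oncogenic transcription factor, was 11.64 in MDA-MB-231 controls and 11.55 on the arrays labelled knockdown, a difference of -0.09 ± 0.17 (adjusted p = 0.71). Its difference in MDA-MB-453 was -0.40, and the other MYC probe gave -0.14 and -0.33 in the 2 lines.

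**Figure D1:**
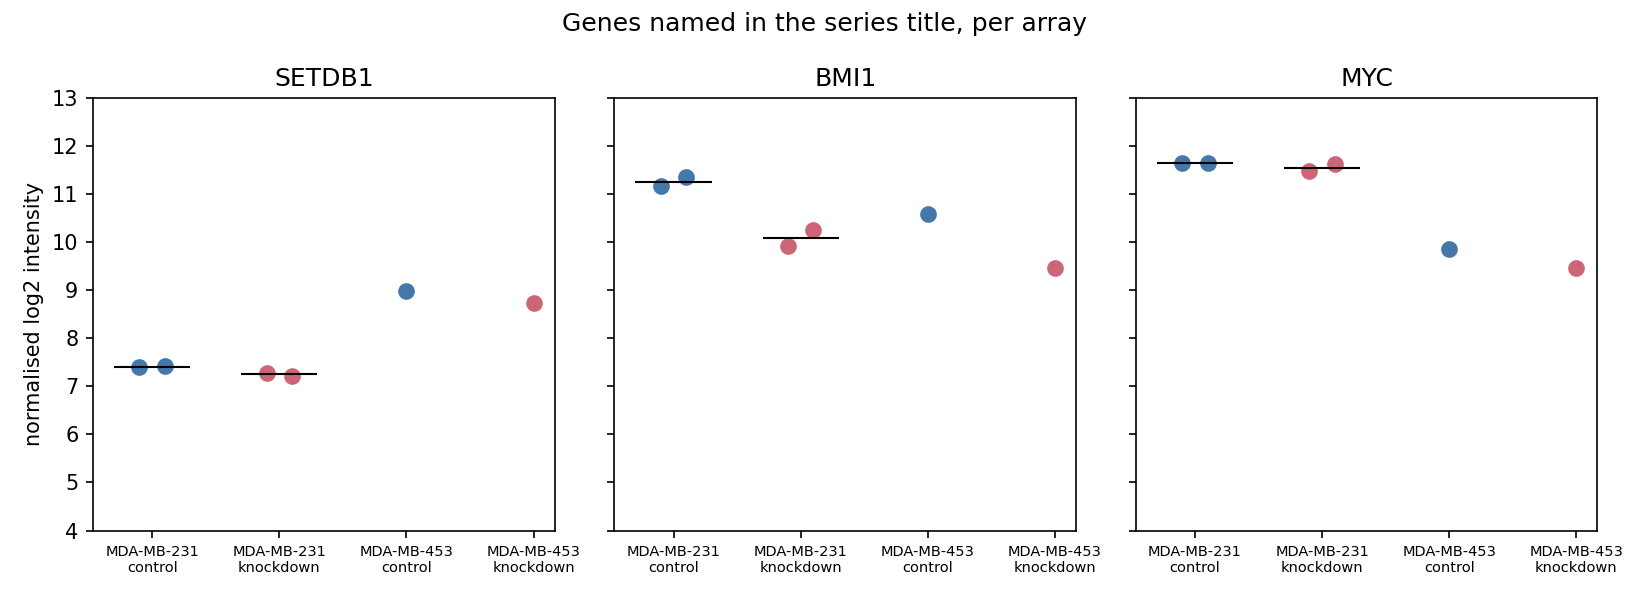
Normalised log2 intensity (vertical axis) of SETDB1, BMI1 and MYC on each array, grouped by cell line and labelled arm; each point is 1 array and each bar the mean of 2 arrays. BMI1 was lower on the arrays labelled knockdown by 1.18 in MDA-MB-231 and 1.14 in MDA-MB-453, while SETDB1 differed by -0.16 and -0.25.

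The comparison within MDA-MB-231 asks which genes differ between cells labelled as SETDB1 knockdown and control. Among the genes that rose most were S100A4, a calcium-binding protein linked to metastasis, by 8.67 ± 0.24 (409-fold), and CST1, a secreted cysteine protease inhibitor, by 7.67 ± 0.18. CD74, the invariant chain of MHC class II, rose from 4.70 to 12.03 and TIMP3, an inhibitor of metalloproteinases, by 6.35 ± 0.17. Several genes went from not detected on either control array to strongly expressed: the adhesion receptor ADGRF5 was at least 162-fold higher, the mesenchymal cadherin CDH11 at least 110-fold, the siderophore-binding lipocalin LCN2 at least 46.0-fold and the epithelial sodium channel subunit SCNN1A at least 43.5-fold. SPANXC, SPANXB1 and SPANXA2, sperm-associated genes of the X chromosome, rose by 7.41, 7.20 and 7.18, and SPANXD was at least 122-fold higher. They are near-identical copies whose probes can bind each other's transcripts, so which of them rose is uncertain.

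Among the largest falls were those of ADAMTS6, a secreted metalloproteinase that was at least 53.6-fold lower, MARCHF4, a membrane-bound ubiquitin ligase, by -5.35 ± 0.18, and KISS1, the precursor of kisspeptin and a suppressor of metastasis, by -5.15 ± 0.24. ESM1, a secreted endothelial proteoglycan, was at least 28.9-fold lower, LRP3, a receptor of the LDL receptor family, at least 18.6-fold and HENMT1, a methyltransferase of small RNAs, at least 14.0-fold. SRGN, the proteoglycan serglycin, fell from 13.39 to 9.33 (-4.06 ± 0.24). ECSCR and ENG, known from endothelial cells, fell from 9.13 to 4.99 and from 8.73 to 4.74. The RNA-binding RBPMS2 fell by 4.04, the esterase BCHE from 8.63 to 4.71 and the synuclein-binding SNCAIP from 8.80 to 4.80. CST1, SPANXC and CD74 were detected on 1 of 2 controls, and ECSCR, ENG, BCHE and SNCAIP on 1 of 2 arrays labelled knockdown, so the sizes of their changes rest in part on background. Adjusted p-values of these 24 genes, the 12 with the largest normalised difference in each direction, were 1.6e-05 or lower, and both arrays labelled knockdown lay on the same side of both controls for each. Which genes are the largest is not determined at the detection floor, where JUP at 52.0-fold exceeds the bounds of SCNN1A and LCN2.

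In all, 2536 genes rose and 2567 fell in MDA-MB-231 (limma, adjusted p below 0.05, 13022 genes). Of these, 1171 rose and 1003 fell by 2-fold or more, and 122 rose and 26 fell by 8-fold or more. Under median scaling 2189 rose and 2912 fell, 1023 and 1230 of them by 2-fold or more. There were 479 genes detected on both arrays labelled knockdown and on neither control, and 310 with the opposite pattern. The number called was 3305 without control replicate 1 and 2893 without control replicate 2. In those fits the remaining control array is assumed to vary like the other group.

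The arms of MDA-MB-231 stood further apart than replicates did, and the differences followed the order of genes along chromosomes. Replicates correlated across genes at 0.990 within the arrays labelled knockdown and 0.993 within the controls, with 73 and 21 genes apart by 2-fold or more. Arrays of opposite arms correlated at 0.919 to 0.931, with 2096 to 2631 such genes. The corresponding pair of MDA-MB-453 arrays correlated at 0.982 with 399 such genes, and arrays of different lines at 0.757 to 0.780 with 4515 to 5076. Over 12527 autosomal genes, the log2 difference of a gene in MDA-MB-231 correlated with the mean of the genes 6 to 25 places away at 0.290. The same value was 0.294 between the control arrays of the 2 cell lines, 0.0727 for the MDA-MB-453 arms, and 0.100 and 0.160 between replicates. In 200 shuffled gene orders the highest value for the MDA-MB-231 arms was 0.0348. The median difference in MDA-MB-231 was -0.52 over the 228 genes of chromosome 13, -0.30 over chromosome 2, -0.25 over chromosome 10 and 0.24 over chromosome 4. In MDA-MB-453 the medians of these were 0.03, 0.01, 0.12 and -0.01. Genes are not independent replicates, so these correlations describe the arrays and carry no p-value.

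**Figure D2:**
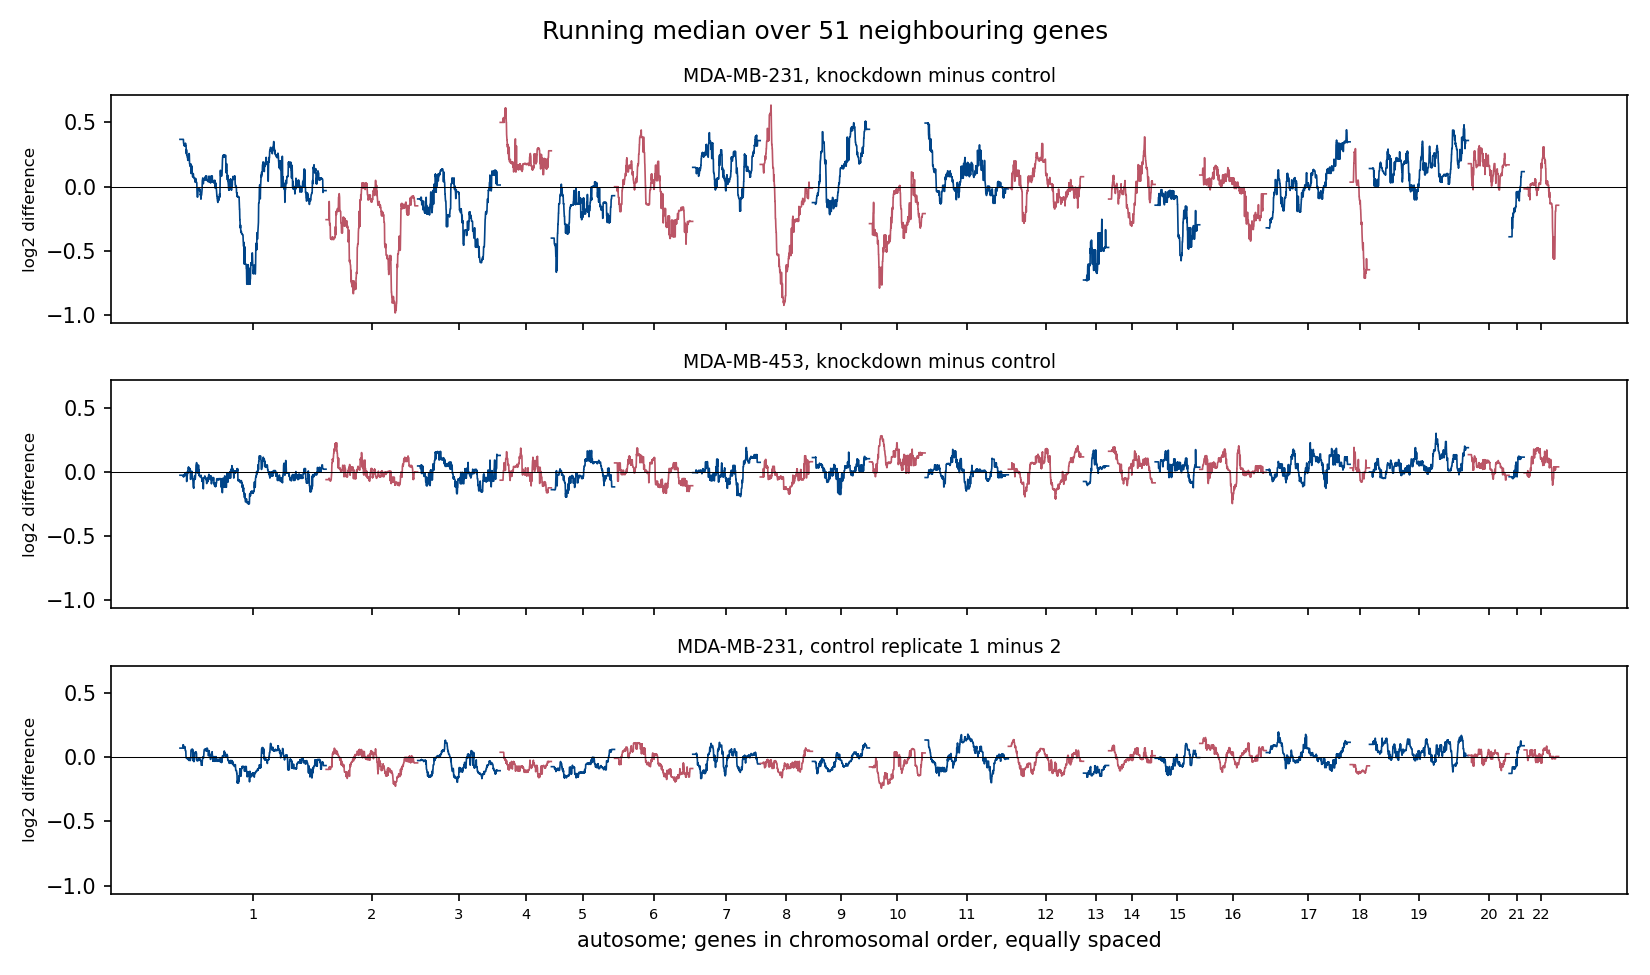
Running median of log2 differences over 51 neighbouring genes (vertical axis) for 12527 genes in chromosomal order on the autosomes (horizontal axis, equally spaced genes, colours alternate between chromosomes). The running median spans -0.98 to 0.63 between the arms of MDA-MB-231 (top), -0.25 to 0.30 between those of MDA-MB-453 (middle) and -0.24 to 0.19 between the MDA-MB-231 control replicates (bottom).

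MYC target genes and genes of G1/S and DNA replication were lower in MDA-MB-231 arrays labelled knockdown. Of 41 measured MYC target genes, 31 fell and 0 rose (32 and 0 adjusted over the list alone), with a median of -0.75 (camera adjusted p = 1.6e-07; adjusted p = 0.263 with an estimated correlation). RRS1, NIP7 and NOLC1, factors of ribosome assembly, fell by 2.26, 1.71 and 1.54, and CAD, which starts pyrimidine synthesis, by 1.33. Of 34 genes of G1/S and DNA replication, 21 fell and 0 rose (21 and 1 adjusted over the list alone), with a median of -0.82 (adjusted p = 1.6e-07; adjusted p = 0.263 with an estimated correlation). MCM4, a subunit of the replicative helicase, fell by 2.01 ± 0.17, RRM2, the small subunit of ribonucleotide reductase, by 2.27 ± 0.20, the clamp loader subunit RFC3 by 1.84 and the phosphatase CDC25A by 1.83. In MDA-MB-453 the medians were -0.41 and -0.38, each at percentile 0 of 10000 random lists, and under median scaling -0.06 and -0.05 where all genes had a median of 0.26. The G2/M list did not follow: of 31 genes 3 rose and 3 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.455). Among them the mitotic kinase CDK1 fell by 1.46 and the kinetochore protein CENPF rose by 1.46. The region-wide shifts described above were present in the same MDA-MB-231 arrays as the falls of MYC target and G1/S genes.

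Epithelial genes were higher in the MDA-MB-231 arrays labelled knockdown, and so were genes of hypoxia and glycolysis and of the interferon response. Of 27 epithelial junction and keratin genes, 15 rose and 1 fell, the same counts as adjusted over the list alone, with a median of 1.37, against 0.87 with no background correction and 0.70 with an offset of 50 (camera adjusted p = 3.7e-06; adjusted p = 0.263 with an estimated correlation). The junction protein JUP rose by 5.70 ± 0.19, KRT19 by 4.48 ± 0.21, the protease inhibitor SPINT2 by 3.74 ± 0.17 and KRT7 by 2.49 ± 0.16, while EPCAM fell by 1.11 ± 0.16. Of 33 hypoxia and glycolysis genes, 18 rose and 2 fell, also adjusted over the list alone, with a median of 0.64 (adjusted p = 1.9e-05; adjusted p = 0.267 with an estimated correlation). They included DDIT4, an inhibitor of mTOR signalling (3.73 ± 0.17), the aldolase ALDOC (3.50), NDRG1 (2.49) and the glycolytic regulator PFKFB4 (2.10). Of 42 interferon-stimulated genes, 22 rose and 2 fell (23 and 3 adjusted over the list alone), with a median of 0.60 (adjusted p = 3.5e-05; adjusted p = 0.6 with an estimated correlation). BST2, which tethers budding virus, rose by 3.73 ± 0.23, IFITM1 by 2.66, the oligoadenylate synthetase OAS2 by 2.45 and the transcription factor IRF7 by 1.82. Of 50 histone genes, 14 rose and 0 fell (13 and 0 adjusted over the list alone; median 0.22; adjusted p = 0.015; adjusted p = 0.6 with an estimated correlation), among them H2BC5 (1.73), H2AC18 (1.35), H3C2 (1.14) and H3C14 (at least 2.15-fold). The region-wide shifts described above were present in the same arrays as each of these groups.

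Markers of both cell lines were among the genes that rose in MDA-MB-231. Of 19 MDA-MB-231 markers, 8 rose and 0 fell, also adjusted over the list alone (median 0.26; camera adjusted p = 0.0095; adjusted p = 0.523 with an estimated correlation; adjusted p = 0.23 among genes detected on all 6 arrays). S100A4, IL6 (3.58), the receptor EPHA2 (1.66) and the membrane protease MMP14 (1.36) were among those that rose. VIM stood at 14.41 and 14.34 in the control and labelled knockdown arms against 7.46 on the MDA-MB-453 control array, AXL at 13.29 and 13.04 against 4.50, and CAV1 at 12.45 and 12.38 against 4.78. Of 17 MDA-MB-453 markers, 8 rose and 2 fell, also adjusted over the list alone (median 0.40; adjusted p = 0.025; adjusted p = 0.52 with an estimated correlation). The luminal genes SPDEF and AGR2 were at least 24.2-fold and at least 20.1-fold higher and KRT19 rose by 4.48, whereas FOXA1, a luminal pioneer factor, was at least 11.2-fold lower. RAB25 and PIP, at 11.63 and 10.76 on the MDA-MB-453 control array, were not detected on any MDA-MB-231 array.

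The other 17 lists did not pass the camera test in MDA-MB-231. Among 26 genes of H3K9 methylation and SETDB1 partners, 4 rose and 6 fell (adjusted p = 0.432), including falls of the chromatin assembly subunit CHAF1B (-1.31) and of UHRF1 (-1.04). Among 23 Polycomb genes, 5 rose and 6 fell (5 and 9 adjusted over the list alone; adjusted p = 0.397), with RBBP7 falling by 2.08 and PCGF6 by 2.21. Among 12 genes of the MYC network, 3 rose and 0 fell (adjusted p = 0.387), among them the MYC antagonists MXD4 (1.68) and MXD3 (1.72). Among 26 CDK inhibitors and p53 targets, 5 rose and 6 fell (adjusted p = 0.846), with CDKN1C rising by 2.72 and TIGAR falling by 1.71. Among 25 apoptosis regulators, 2 rose and 4 fell (2 and 3 adjusted over the list alone; adjusted p = 0.932). The survival factor BCL2 fell by 1.58, and the death-promoting BIK was at least 2.69-fold higher. Where no count over the list alone is given for these lists, it equals the count over all genes.

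Among 14 breast cancer stem cell markers, 7 rose and 3 fell (adjusted p = 0.0774), and the Notch ligand JAG1 and the integrin ITGB4 rose by 3.86 and 3.90. Among 29 mesenchymal and matrix genes, 11 rose, led by S100A4 and CDH11, and 8 fell (adjusted p = 0.505). Among 24 inflammatory genes, 10 rose and 4 fell (11 and 6 adjusted over the list alone; adjusted p = 0.246), with IL6 up by 3.58 and the growth factor CSF3 down, at -1.89. Among 20 cholesterol genes, 6 rose and 4 fell (6 and 5 adjusted over the list alone; adjusted p = 0.397), with INSIG1 rising by 2.09 and TM7SF2 by 1.60. Among 31 genes of the unfolded protein response and ATF4 targets, 8 rose and 6 fell (8 and 7 adjusted over the list alone; adjusted p = 0.325). The serine synthesis enzyme PHGDH rose by 3.29 and DDIT4 by 3.73. Among 22 immediate-early genes, 6 rose and 1 fell (adjusted p = 0.397), including rises of KLF2 (1.43) and JUND (1.33).

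Among 363 zinc finger (ZNF) genes, 79 rose and 37 fell (75 and 34 adjusted over the list alone; camera adjusted p = 0.0939), and ZNF467 and ZNF518B rose by 4.30 and 2.40. Among 22 cancer-testis genes, 8 rose and 3 fell (9 and 4 adjusted over the list alone; adjusted p = 0.0545), led by SPANXB1 and SPANXD. Among 16 clustered protocadherins, 3 rose and 0 fell over all genes and 0 and 0 adjusted over the list alone (adjusted p = 0.571), with PCDHB13 at least 1.35-fold higher and PCDHB2 at 0.53. Among 72 ribosomal protein genes, 4 rose and 10 fell (4 and 7 adjusted over the list alone; adjusted p = 0.397). RPL22L1 fell by 1.88 and RPL7 by 1.56. Among 74 genes of mitochondrial oxidative phosphorylation, 9 rose and 16 fell (9 and 14 adjusted over the list alone; adjusted p = 0.846), with the ATP synthase subunits ATP5PB and ATP5MC3 falling by 1.59 and 1.43. The median and mean of the mesenchymal, CDK inhibitor, apoptosis, immediate-early and oxidative phosphorylation lists had opposite signs, and no direction is given for them. With an estimated correlation 0 of the 25 lists passed. That version rests on 2 residual degrees of freedom, so it cannot tell whether correlation between genes accounts for the calls. Among the lists that passed, the estimate was 0.171 for interferon-stimulated genes and 0.127 for histone genes, above the preset 0.01. The camera calls of these lists rest on that lower preset. The next highest estimate was 0.0383, for MDA-MB-231 markers. For hypoxia genes the estimate was 0.00989, near the preset 0.01. Their unadjusted camera p was 3.01e-06 with the preset and 0.0428 with the estimate.

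**Figure D3:**
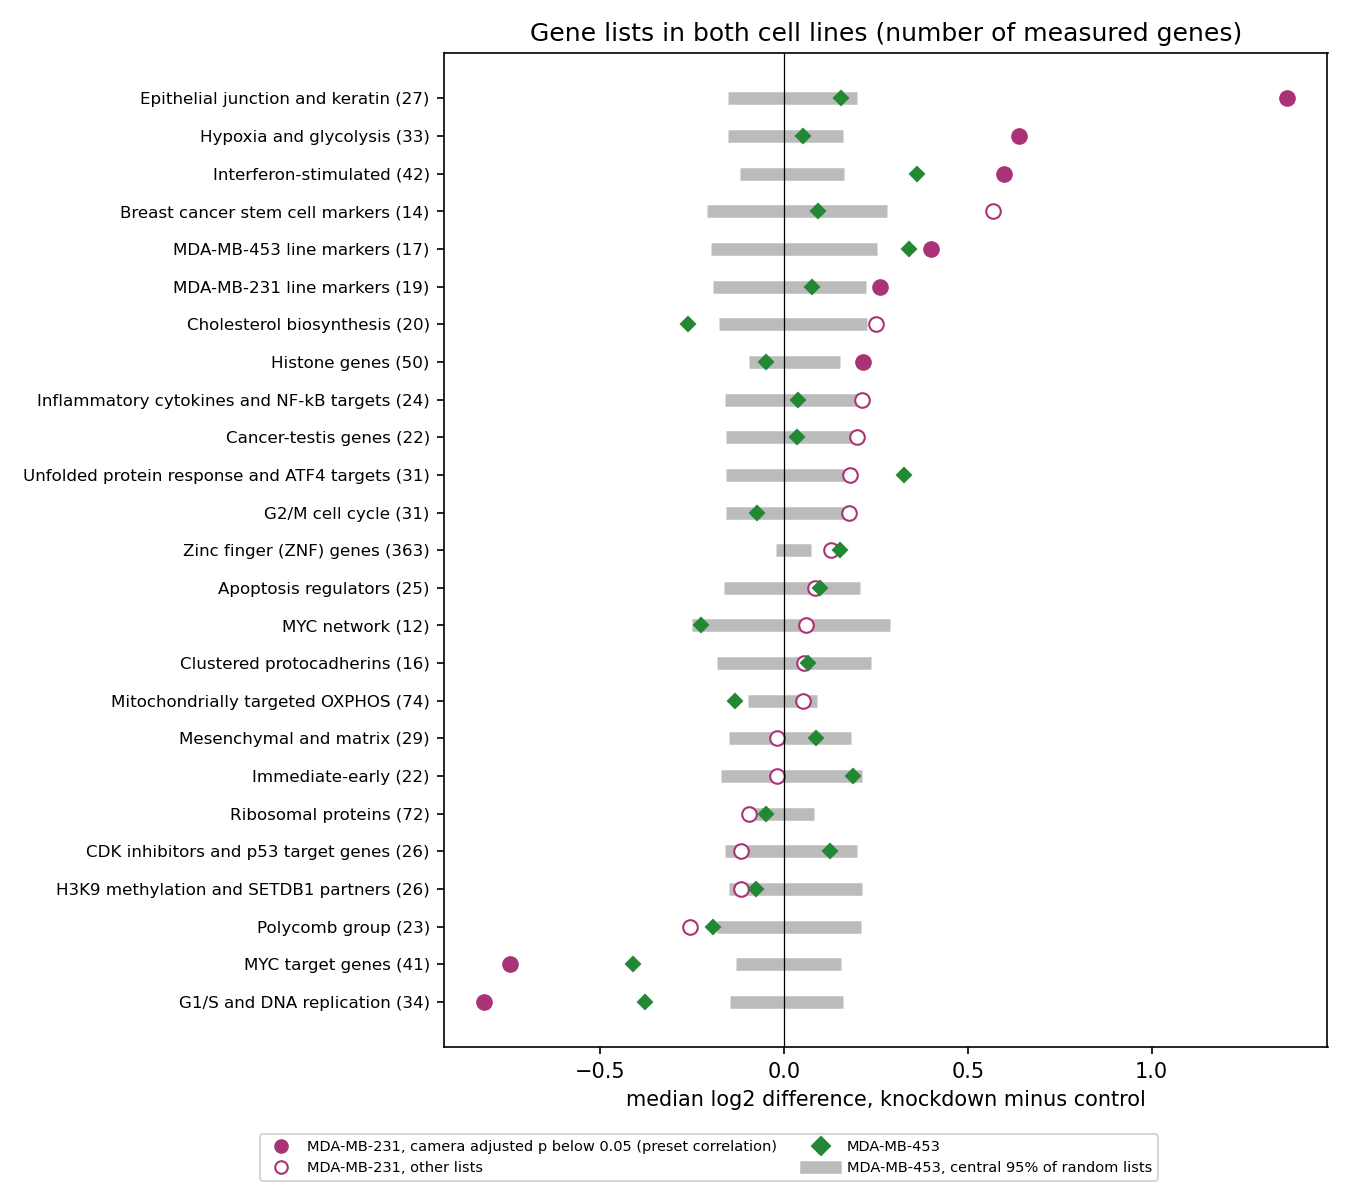
Median log2 difference between arms (horizontal axis) of each of the 25 gene lists in MDA-MB-231 (circles, filled for lists past the camera test with a preset correlation) and in MDA-MB-453 (diamonds), with grey bars for the central 95% of 10000 random lists in MDA-MB-453. The MYC target and G1/S medians lie below 0 in both lines (-0.75 and -0.82, -0.41 and -0.38), and the epithelial median is 1.37 in MDA-MB-231 and 0.15 in MDA-MB-453.

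The comparison within MDA-MB-453 sets 1 array against 1 array and has no replicate check. DHRS2, a mitochondrial dehydrogenase, was higher on the array labelled knockdown by 5.64, and S100P, a calcium-binding protein not detected in the control, by at least 12.1-fold. GDF15, a stress-induced cytokine, was higher by 3.75, the mammary secretoglobin SCGB2A2 by 3.45, the growth factor-binding protein IGFBP3 by 3.39, the serine protease PRSS23 by 2.87 and ALB by 2.76, and the cell-surface peptidase MME stood at 5.97 and 8.96. The most reduced were ID1 (-3.07) and ID3 (-2.01), inhibitors of basic helix-loop-helix factors, S100A8 (-2.71) and S100A9 (-2.20), which together form calprotectin, and DOCK2 (-2.64), an activator of Rac. CARD10, not detected on the array labelled knockdown, was at least 3.46-fold lower, and BBOX1, of carnitine synthesis, and the thymosin TMSB15A differed by -1.79 and -1.74. In all, 196 genes were higher and 203 lower by 2-fold or more, and 5 and 1 by 8-fold or more. Under median scaling in place of quantile normalization these counts were 681 and 46, and the median over all genes was 0.26 in place of 0.02. The control array was the dimmest of the 6 (median intensity 47.9) and the array labelled knockdown the brightest (60.4). Whether that bears on these counts was not tested.

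Some lists stood apart in MDA-MB-453 as well. Interferon-stimulated genes had a median of 0.36 (percentile 100 of random lists), genes of the unfolded protein response and ATF4 targets 0.33 (percentile 99.99), ZNF genes 0.15 (percentile 100) and MDA-MB-453 markers 0.34 (percentile 99.7). Random lists ignore correlation between members, estimated in MDA-MB-231 at 0.171 for interferon genes and 0.371 for oxidative phosphorylation genes, so these percentiles are no test with replicates. Relative to the median of all genes, these medians were 0.26 to 0.34, 0.28 to 0.42, 0.09 to 0.18 and 0.26 to 0.34 under the scalings tried, and those of the MYC target and G1/S lists -0.43 to -0.32 and -0.40 to -0.31. Cholesterol genes had a median of -0.26 (percentile 0.42), oxidative phosphorylation genes -0.13 (percentile 0.37) and Polycomb genes -0.19 (percentile 1.89). All 3 changed sign under median scaling, with values of -0.28 to -0.15, -0.15 to -0.14 and -0.21 to -0.09 relative to all genes.

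The effect across both lines was estimated in an additive model of 3 arrays against 3. S100P rose (adjusted p = 0.0021) and was at least 30.2-fold higher in MDA-MB-231 and at least 12.1-fold in MDA-MB-453. GDF15 rose as well (adjusted p = 0.00057), and was at least 13.4-fold higher in MDA-MB-231 and higher by 3.75 in MDA-MB-453. TEX19, a germ-cell gene, rose by 2.84 (adjusted p = 0.0021), the matrix protein THBS1 by 1.86 and the retinal reductase DHRS3 by 1.79 (both adjusted p = 0.0315). THBS1 and DHRS3 were no longer called when any MDA-MB-231 array was left out (adjusted p 0.22 to 0.28). These 5 genes rose and 0 fell in limma, against 2056 and 1929 at an unadjusted p below 0.05, and each was higher on the 3 arrays labelled knockdown than on their line's controls. The balance depends on the settings: among genes detected on all 6 arrays 452 rose and 504 fell, and with no background correction 136 and 169. The count moved between 1 and 956 with the settings tried, as given in the closing part on processing.

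Of the genes called in MDA-MB-231, 62.4% (95% exact binomial interval 61.1 to 63.7, which treats genes as independent) had the same sign in MDA-MB-453. Under median scaling the share was 54.5%. For those that rose the share was 62.8%, against 50.4 to 53.8% for random genes of matched intensity, and for those that fell 62.1% against 46.2 to 49.6%. The lines share no control arrays. There were 36 genes higher by 2-fold or more in both lines, where independent lists would share 17.6, and 49 lower in both, where independent lists would share 15.6. Under median scaling, tried after the data were seen, 97 were higher in both (53.5 for independent lists) and 8 lower (4.34). BMI1, KISS1, CDK1, RRM2, CHAF1B and TIGAR were among the 49, and S100P, GDF15, OAS2 and PRSS23 among the 36. Up in MDA-MB-231 and down in MDA-MB-453 were 20 genes (18.3 for independent lists), and the reverse held for 9 (15.1). Under median scaling these were 7 (3.61) and 32 (64.3), so there the excess was not limited to genes moving the same way. Across all genes the differences in the 2 lines correlated at r = 0.167 and rho = 0.201.

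**Figure D4:**
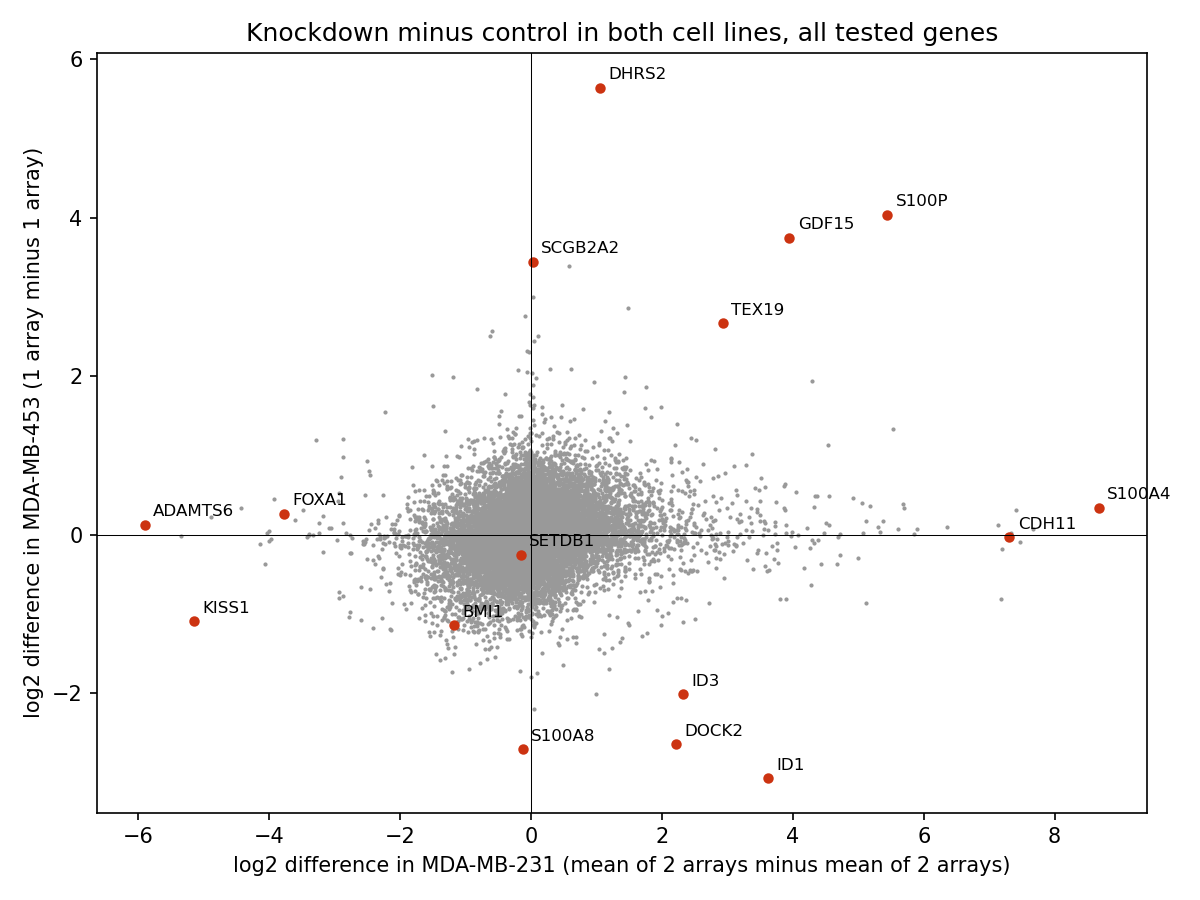
Log2 difference between the arms in MDA-MB-231 (horizontal axis, mean of 2 arrays minus mean of 2 arrays) and in MDA-MB-453 (vertical axis, 1 array minus 1 array), with a point for each of 13022 genes and red points for the labelled genes. TEX19 lies at 2.93 and 2.67, DHRS2 at 1.06 and 5.64, KISS1 at -5.15 and -1.09 and ID1 at 3.63 and -3.07, while places of genes not detected in an arm rest on background values.

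The difference of the effect between lines was tested in the fit of 4 groups. S100A4 (adjusted p = 2.1e-05), SPANXA2 (2.37e-05), CST1 and ADGRF5 (both 1.28e-05) were among the genes with the largest difference toward a higher effect in MDA-MB-231. S100A4, CST1 and ADGRF5 were not detected on the MDA-MB-453 control array, nor SPANXA2 on the array labelled knockdown of that line, nor ADGRF5 on the MDA-MB-231 controls, so the sizes and order of these 4 are not determined. In the other direction stood ADAMTS6 (2.1e-05), MARCHF4 (4.41e-05), ESM1 (4.56e-05) and LRP3 (5.74e-05), of which only LRP3 was detected on the MDA-MB-453 control array. ID1 and ID3 moved in opposite directions, with differences of 3.63 and -3.07 for ID1 and 2.32 and -2.01 for ID3 (adjusted p of the difference 1.28e-05 and 1.05e-04). In all, the effect was more positive in MDA-MB-231 for 950 genes and more negative for 816. Under median scaling the counts were 688 and 2083, without control replicate 1 they totalled 885, without control replicate 2 they totalled 726, and without replicate 2 labelled knockdown 2678.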

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

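The tests of SETDB1's signal over background and of a regional technical trend were chosen after the results were seen, and the other tests of this part before.

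The 2 arms of MDA-MB-231 arrays differed by 5103 genes, in a pattern that ran along chromosomes. The regional SD between the arms (0.262) was 4.73 times the larger one between replicates, which argues against a trend of the kind seen there. The lowest count under the other background and normalization settings was 4973, which argues against normalization. For admixed MDA-MB-453 RNA, a median difference over 1 was predicted for the 206 genes at least 16-fold higher in that line. The median was 0.27, which argues against an admixture large enough for that. A smaller admixture is not excluded. Of the 206 genes 82 were called as risen, and the lower and upper quartiles of their differences were -0.01 and 1.56. A different cell line, clone or sub-line in 1 arm stays a candidate explanation. The correlation between neighbouring genes was 0.988 times that between the 2 cell lines, and the regional SD was 0.262 against 0.426. The control replicates reached 0.544 times that correlation, above the 0.5 set for this explanation, so the correlation does not decide it. Nor does it tell which arm would differ, and no DNA was measured. Of 19 MDA-MB-231 markers, 8 were higher in the arm labelled knockdown and 0 fell, while VIM, AXL and CAV1 were high in both arms. Loss of SETDB1 repression also remains open, because 60.7% of the 789 genes detected in 1 arm alone were detected in the arm labelled knockdown, between the bounds set for and against it. With a change of at least 4-fold, 55 genes were detected in that arm alone and 20 in the control arm alone, so the share depends on the cut-off. Between the single MDA-MB-453 arrays 744 genes were detected only on the array labelled knockdown and 389 only on the control. These arrays had the highest and lowest median intensities of the 6, 60.4 and 47.9. The share therefore does not decide it. For the genes that differ between the MDA-MB-231 arms, knockdown and a different line or clone cannot be told apart, as the labels name no other hairpin in MDA-MB-231.

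SETDB1 was not measurably lower on its probe while BMI1 was lower in both lines. A probe too near background is not what the values show: its intensity in the MDA-MB-231 controls was 4.54 times the median of undetected probes, and the 95% interval of the change ends at -0.53. A fall in transcripts that this probe does not report, or arrays whose label does not match their knockdown, may remain, and neither was tested. No biological explanation was tested for this pattern.

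Across both lines 5 genes were called, and 1 of the 10 splits of the 6 arrays into 3 and 3, the real one, gave as many. The highest of the other splits gave 3 genes, and 10 splits are too few for a share under 0.05. That split kept the MDA-MB-231 arms together and swapped the MDA-MB-453 arrays. The remaining splits mixed the MDA-MB-231 arms and gave 0 genes, so the comparison rests on 5 against 3 genes.

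Many single genes responded differently in the 2 lines by the limma test of the difference itself (adjusted p below 0.05), with MDA-MB-453 assumed to vary like MDA-MB-231. The values that follow are the log2 effect in MDA-MB-231 minus that in MDA-MB-453. Where a probe was not detected in an arm the value rests on background, so that neither its size nor its place in an order is determined. This holds within MDA-MB-231 for ADGRF5, CDH11, SPANXD, LCN2, SCNN1A, ADAMTS6, ESM1, LRP3, HENMT1, S100P, SPDEF, AGR2, FOXA1, BIK and H3C14, for SCGB2A2, MME, S100A8, S100A9, BBOX1 and TMSB15A in both of its arms, and for any gene not detected in MDA-MB-453. Among the genes most raised in MDA-MB-231 they were 8.33 for S100A4, 7.99 for SPANXA2, 7.60 for CST1, 7.57 for ADGRF5, 7.38 for SPANXB1, 7.33 for CDH11, 7.31 for CD74, 7.10 for SPANXC, 7.02 for SPANXD, 6.25 for TIMP3, 5.84 for LCN2 and 5.82 for SCNN1A. Among those most reduced there they were -6.03 for ADAMTS6, -5.34 for MARCHF4, -5.12 for ESM1, -4.76 for LRP3, -4.37 for BCHE, -4.06 for KISS1, -4.06 for RBPMS2, -4.05 for ENG, -4.02 for ECSCR, -3.92 for SNCAIP, -3.91 for HENMT1 and -3.70 for SRGN.

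Among the genes with the largest differences in MDA-MB-453 the values were -4.58 for DHRS2, -3.41 for SCGB2A2, -2.97 for MME, -2.85 for ALB, -2.81 for IGFBP3, -1.39 for PRSS23 and 1.40 for S100P. They were 6.69 for ID1, 4.85 for DOCK2, 4.33 for ID3, 3.0 for CARD10, 2.58 for S100A8, 2.24 for S100A9, 1.83 for TMSB15A and 1.79 for BBOX1. ID1, ID3, DOCK2 and CARD10 rose in MDA-MB-231 and were lower in MDA-MB-453.

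Among list members with a positive value were the epithelial genes JUP (5.36), KRT19 (4.45), SPINT2 (3.32) and KRT7 (1.98), the luminal genes AGR2 (4.98) and SPDEF (4.45), and the hypoxia genes DDIT4 (3.61), ALDOC (3.33), PFKFB4 (2.37) and NDRG1 (2.36). The interferon-stimulated genes BST2 (3.72), IFITM1 (2.23), IRF7 (1.66) and OAS2 (1.23), the histone genes H2BC5 (1.79), H3C14 (1.71), H3C2 (1.66) and H2AC18 (1.31), and IL6 (3.44), MMP14 (1.25) and EPHA2 (1.08) were also positive. So were ZNF467 (4.36), ITGB4 (3.77), CDKN1C (3.59), JAG1 (3.24), INSIG1 (3.08), PHGDH (2.41), MXD3 (2.04), ZNF518B (1.73), BIK (1.53), TM7SF2 (1.32), JUND (1.17) and MXD4 (1.14). Negative values stood for FOXA1 (-4.05), RBBP7 (-2.22), RPL22L1 (-2.19), MCM4 (-2.06), CSF3 (-1.85), RRS1 (-1.85), NIP7 (-1.59), PCGF6 (-1.59), BCL2 (-1.50), CAD (-1.16), RFC3 (-1.15) and CDC25A (-1.11).

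Whole lists differed between the lines too by camera on that difference with the preset correlation. Their medians in MDA-MB-231 were -0.75 for MYC targets (adjusted p = 0.024), -0.82 for G1/S genes (0.018), 1.37 for epithelial genes (1.3e-05), 0.64 for hypoxia genes (6.4e-05), 0.20 for cancer-testis genes (0.028), 0.22 for histone genes (0.024) and 0.26 for MDA-MB-231 markers (0.018). With an estimated correlation, which leaves 2 residual degrees of freedom, the adjusted p was 0.53 or more for each.

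Outside the comparisons, 2836 of the 17986 probes with no gene in the annotation used here were detected on all 6 arrays, which is 15.8% of them. They were not tested.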

How the results depend on the processing

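The alternatives for genes apart by 2-fold in both lines were chosen after the data were seen, and the others before. No alternative reversed a called value, and 1592 of 1707 recomputed values were classed as unchanged. A tested value was unchanged if it kept its side of the threshold, and a count if it stayed within 1.5-fold. The same-sign share had to stay within its binomial interval, and single-gene differences in MDA-MB-453 within a margin set from the limma standard error. Values of MDA-MB-453 alone cannot change when an MDA-MB-231 array is left out, and they were counted too. The cause of the moves below was not tested, except where a setting tests fewer genes or arrays. The effect across lines called 305 genes with no background correction, 72 with an offset of 50, 11 with median scaling, 304 with the authors' processed values, 956 among genes detected on all 6 arrays, 445 with an intensity trend and robust prior, and 1 to 3 with an array left out. THBS1 and DHRS3 lost their call when any MDA-MB-231 array was left out (adjusted p 0.22 to 0.28), and S100P and TEX19 without replicate 2 labelled knockdown (adjusted p = 0.066). THBS1 also lost it without the detection filter (adjusted p = 0.069).

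The count in MDA-MB-231 was 2174 with an absolute log2 change of at least 1, and 2893 to 5246 with an array left out. The difference between lines was called for 2771 genes with median scaling, 1070 among genes detected on all 6 arrays, and 726 to 2678 with an array left out. Genes apart by 2-fold in MDA-MB-453 numbered 200 with no background correction, 183 with an offset of 50, 727 with median scaling, 201 with the authors' processed values and 252 among genes detected on all 6 arrays. The share with the same sign in both lines was 54.5% with median scaling, 65.2% among genes detected on all 6 arrays, and 60.9 to 63.6% with an array left out. Of 25 lists 8 passed the camera test, 0 with an estimated correlation, and 13 with fry, which does not set a list against other genes. Fry shared 7 of the 8 and not the histone list (adjusted p = 0.067), and its others were the MYC network (0.031), mesenchymal (0.014), stem cell (0.017), unfolded protein response (0.0072), cholesterol (0.033) and cancer-testis (0.012) lists. Genes higher by 2-fold in both lines numbered 17 to 97 over the other background and normalization settings, and those lower in both 8 to 33, each above the number for independent lists. The main setting gave 36 and 49. SETDB1 stayed between -0.06 and -0.24, with adjusted p of 0.31 to 0.81.

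Replicate numbers do not pair the arrays: differences of replicates 1 and 2 correlated at 0.0713 between the arms. With the replicate block 4919 genes were called in MDA-MB-231, 8 lists passed, SETDB1 was at -0.16 and the effect across lines called 3 genes. Slide as a block was not run, since the files name no slides, and only 1 SETDB1 probe could be tried. With limma and camera at the preset correlation, single genes and lists lost 21 calls and gained 8 over the other settings, among them the losses of the histone list without control replicate 2 (adjusted p = 0.061) and of the MDA-MB-231 markers among genes detected on all 6 arrays (0.23). With that test calls were gained by the cancer-testis list in 4 settings (lowest 0.0131), the stem cell markers in 2 (lowest 4.92e-05) and the ZNF list in 2 (lowest 0.0342).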

Other observations

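Genes of MHC class II antigen presentation were higher in the MDA-MB-231 arrays labelled knockdown, a group chosen after its values were seen. Of 12 measured genes 11 rose and 0 fell (limma, adjusted p below 0.05), 8 of them by 2-fold or more, with a median difference of 3.41. HLA-DRA, a chain of the presenting receptor, rose by 5.18 ± 0.21, and HLA-DMA and HLA-DMB, which load peptides, by 3.18 ± 0.18 and 3.63 ± 0.19. CIITA, the transcriptional activator of the class, was detected on neither control array and was at least 1.27-fold higher (adjusted p = 0.043). In MDA-MB-453 the median was -0.05, with 0 of the 12 genes higher or lower by 2-fold. Camera gave an unadjusted p of 2.5e-10 with the preset correlation and a p of 0.0217 with an estimated correlation, and neither is independent of the choice. Genes of this class have near-identical copies, so values of single members are uncertain. The region-wide shifts along chromosomes were present in the same arrays, and whether members of this group lie near each other was not analysed.

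Secreted cystatins, TIMP inhibitors and S100 genes, each tested as a group of its own, were also chosen after their values were seen. All 6 measured secreted cystatins rose, among them CST4, at least 39.0-fold higher, and CST2, at least 9.26-fold higher, as did all 4 TIMP inhibitors of metalloproteinases, with TIMP1 at 1.66 and TIMP2 at 1.69. Of 14 S100 genes 10 rose, 0 fell and 4 were not called, and those that rose included S100A3 by 3.34 ± 0.25, S100A2 by 2.35 ± 0.20 and S100A6 by 1.64 ± 0.19. In MDA-MB-453 the medians of the 3 groups were 0.23, 0.13 and -0.03, and among the S100 genes 1 was higher and 2 were lower by 2-fold. With an estimated correlation camera gave unadjusted p of 0.125, 0.0551 and 0.237 for the 3 groups in MDA-MB-231. For these groups too, region-wide shifts were present in the same arrays. Members that lie near each other on a chromosome would not be separate observations, and their places were not analysed.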
